A study of Mus musculus with 12 samples.

How the data were processed

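Total RNA was sequenced from N2A cells, a mouse neuroblastoma line, that had been transfected with a biotin-tagged mimic of the microRNA miR-135a or with a biotin-tagged negative control mimic. RNA bound to the tagged mimic was recovered on beads (the pulldown), and RNA of the transfected cells was also taken without that step (the input). The 12 samples form 4 groups of 3 by mimic and fraction, taken from the sample titles. Nothing in the labels says whether the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

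The authors deposited 1 table of raw counts per gene for the pulldown and 1 for the input, each with 38826 Ensembl genes. Per the submitters' processing notes, TopHat2 2.0.13, HTSeq and edgeR 3.12.1 were used with genome build GRCm38.p6, and per the labels' protocols the libraries came from a stranded total RNA kit. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so counts of gene families with near-identical copies are uncertain. The deposited count columns name the mimic but not the replicate, so libraries are numbered here by column order, which pairs nothing across groups. The authors also deposited log2 fold changes with p-values and false discovery rates for the genes they called in each fraction, and these values are named as the authors' where they are printed. A further deposited list pairs the 587 genes the authors called higher in the pulldown with gene symbols. Its log2 fold changes differ from those of the call table by at most 5e-10. Per the file headers, the authors searched the 5′ UTR, coding and 3′ UTR sequences of these 587 genes with miRanda 3.3a at a score threshold of 140 and an energy threshold of 1 kcal/mol, and the deposited values are an alignment score and a folding energy per site.

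Only these 587 genes could be named. The reference table used here (RefSeq, GRCm38.p6) carries no Ensembl identifiers, and the files do not pair the other identifiers with names. Of the 587 symbols, 550 matched the reference by symbol, 28 by synonym and 9 by neither, and 571 were protein-coding genes. Genes that were lower in the pulldown therefore have no names here, and every count over a gene list covers only members that the authors had already called higher in the pulldown. Such counts are not independent evidence of that direction.

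Each fraction was fitted by itself with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood F test, 2-sided), with genes called at a Benjamini-Hochberg adjusted p under 0.05. All 12 libraries were fitted together for the difference between the mimic effect in the pulldown and in the input, and for the pulldown over the input with each mimic. The standard error of a log2 fold change is its size divided by the square root of F. CPM values are edgeR's counts scaled to a common library total with the TMM factors of the fit named. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 for lists with at least 3 members, in the pulldown against the other named genes and in the input against all other tested genes. The planned search of 3′ UTR sequences for seed matches, with control heptamers, was not possible without sequences. It was replaced by the authors' predicted sites: genes with a site matching positions 2 to 8 of the microRNA (seed site) were compared with genes whose searched sequences held no predicted site, over the longest sequence of each gene.

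Gene lists fixed before the data were examined covered reported miR-135 targets, MEF2 factors, microRNA machinery, biotin carboxylases, cytosolic ribosomal proteins, nuclear and mitochondrial respiratory genes, histones, small nuclear and nucleolar RNAs, nuclear long noncoding RNAs, zinc finger genes (symbols of Zfp and a number), glutamate and GABA synapse, epilepsy channels, synaptic vesicle, axon guidance, cytoskeleton and motors, Wnt, TGF-beta, interferon, cell cycle, p53, unfolded protein response, cholesterol synthesis, immediate-early genes, neuronal lineage, and markers of astrocytes, oligodendrocytes, microglia, fibroblasts and endothelial or blood cells. The rule for named genes, fixed at the same time, took genes past the threshold. Symbols that are gene model or clone names, such as those ending in Rik, were left out. A mean of at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups were required. The rule took the 12 highest and 10 lowest in the pulldown, 8 and 8 in the input, and 6 and 6 in the other comparisons. To these it added Mef2a, the reported targets, and up to 4 members of each list with the smallest adjusted p.

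Alternatives were DESeq2 1.42.0, limma voom, other scaling factors, other count filters, the edgeR exact test, all 12 libraries in each fit, other set tests, and leaving out each library. Leaving out both pulldown libraries that stood apart from the rest was added after the data had been seen, as was the exact test for the overlap of pulldown and input calls. The pipeline was tested on simulated counts. With 10683 genes in the pulldown it recovered 7% of 100 genes changed 2-fold and 59% of 100 changed 4-fold, and 4.35% of its calls were false. With 13454 genes in the input it recovered 65% and 95%, and 9.09% of its calls were false.

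Library totals ranged from 7597489 to 14571530 counts in the pulldown and from 28261414 to 63967640 in the input. The biological coefficient of variation was 0.366 in the pulldown and 0.193 in the input.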

Results

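To find RNAs bound by miR-135a, a microRNA studied here in the context of temporal lobe epilepsy, RNA captured with the biotin-tagged miR-135a mimic was compared with RNA captured with a control mimic in N2A cells, with 3 libraries in each of 4 groups. The control pulldown libraries held 7597489, 14571530 and 14196821 counts and the miR-135a pulldown libraries 9730547, 8976842 and 8400169. The control inputs held 30923209, 63967640 and 34131575 counts and the miR-135a inputs 32115761, 28261414 and 33271848. The 10 most abundant genes took 58.4% to 75.3% of the counts in a pulldown library and 8.9% to 31.4% in an input library. Replicates differed far beyond sampling noise (chi-square per degree of freedom of 23.2 or more in each pair), so none was a duplicate. Control pulldown 1 detected 12146 genes and miR-135a pulldown 3 detected 12555, against 14073 to 15644 in the other 4 pulldown libraries, and their rank correlations with replicates were 0.87 to 0.89, against 0.965 and 0.973 for the remaining pairs.

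Zinc finger genes led the RNAs that were higher in the miR-135a pulldown. Zfp729b, on chromosome 13 from 67589439 to 67609707, rose from 3.64 ± 0.102 to 90.2 ± 49.5 CPM (SD, n = 3 each), a log2 fold change of 4.63 (SE 0.412, adjusted p = 0.000167, edgeR quasi-likelihood test). Zfp35, on chromosome 18 from 23989634 to 24005371, rose from 8.49 ± 2.81 to 104 ± 32.3 CPM (log2 fold change 3.6). Zfp729a, Zfp300, Zfp143, Zfp715, Zfp235, Zfp111, Zfp942 and Zfp109 rose as well, by log2 fold changes of 4.89, 4.86, 4.43, 3.98, 3.79, 3.74, 3.39 and 3.19. Zfp729a and Zfp729b are neighbours with related names, and reads shared between such copies were not resolved here. Both lie outside the zinc finger list, which took symbols of Zfp and a number without a letter after it. Of the 52 zinc finger genes of the list that were tested, 38 passed the threshold over all genes, as did 423 of the 584 named genes tested. Adjusted over the list alone all 52 passed, as did the tested members of every other list. All had been selected as higher in these libraries, so this tests little. Their median log2 fold change was 2.31, against 1.19 for the other named genes. camera, which compares test statistics rather than fold changes, did not separate the zinc finger genes from the other named genes (adjusted p = 0.862, and 0.961 with an estimated correlation). With library size scaling the camera adjusted p was 0.00656, and without both libraries that stood apart it was 0.00042.

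The largest rise belonged to Rny3, a small Y RNA encoded on chromosome 6 from 47781624 to 47781724, which went from 8.46 ± 4.58 to 695 ± 510 CPM (SD, n = 3 each; log2 fold change 6.33, SE 0.611, edgeR adjusted p = 0.000179). Nr3c1, the glucocorticoid receptor, rose from 10.6 ± 3.22 to 110 ± 58.8 CPM (log2 fold change 3.38). Klf6, an immediate-early transcription factor and the 1 named member of that list, rose by 2.45 on the log2 scale.

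Of the 24 genes on the microRNA machinery list, 6 were among the genes the authors had called higher in the pulldown. All 6 passed in the refit, as did 423 of the 584 named genes tested: Ddx6, a helicase of translational repression (log2 fold change 2.43), the GW182 scaffold genes Tnrc6a (2.14) and Tnrc6b (1.83), the Argonaute genes Ago2 (0.98) and Ago3, and the decapping enzyme gene Dcp2. Their median was 1.51, and the list did not pass against the other named genes (camera adjusted p = 0.614; 0.961 with an estimated correlation). It passed with library size scaling (0.0312) and without miR-135a pulldown 2 (0.00816), and without miR-135a pulldown 3 the difference in medians vanished (adjusted p = 0.956). Of 63 axon guidance genes 10 were among the authors' genes, and 9 of these passed, among them the receptors Nrp1 (1.37), Neo1 (1.17), Unc5b (1.21) and Plxna1 (1.32), and this list did not pass against the other named genes either (camera adjusted p = 0.614).

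The other lists had still fewer members among the authors' genes: 4 of 32 for TGF-beta, 5 of 26 for unfolded protein response, 4 of 25 for cholesterol synthesis, 4 of 15 for mitochondrially encoded, 3 of 78 for ribosomal protein, 2 of 30 for epilepsy channel, 2 of 28 for neuronal lineage, 2 of 31 for cell cycle, 2 of 33 for synaptic vesicle and 1 of 35 for Wnt genes. The counts that follow cover these members alone. In the refit 3 of 4 TGF-beta pathway genes rose, including the receptors Acvr1b (2.24) and Tgfbr1 (1.36), and 4 of 5 unfolded protein response genes, including the chaperone gene Canx (1.13). Of 4 cholesterol synthesis genes 3 rose, Sc5d, Stard4 and Sqle, as did 3 of 4 mitochondrially encoded genes, mt-Nd6, mt-Rnr2 and mt-Co3, and 2 of 3 ribosomal protein genes, Rps29 and Rpl39. The epilepsy channel genes Cacna1c and Kcnq2, the neuronal lineage genes Ncam1 and Ret, the cell cycle genes Mcm3 and Mcm4, Lrp6 of the Wnt list, and Syt11 of 2 synaptic vesicle genes rose. Many of these calls were lost when 1 library was left out. Fewer samples also weaken a test, so a lost call alone does not show dependence on 1 library. Of the 47 called genes with names that the rule picked in the pulldown, 14, 18 and 16 were no longer called without control pulldown 1, 2 or 3, and 24, 5 and 16 without miR-135a pulldown 1, 2 or 3. Rpl39 (edgeR adjusted p of 0.0532 to 0.192) and Mcm3 (0.052 to 0.15) were lost whichever of the 6 was left out. The log2 fold change ranged from 0.742 to 1.35 for Rpl39 (1.09 with all libraries) and from 0.797 to 0.924 for Mcm3 (0.83). The edgeR adjusted p reached 0.119 for Sqle, 0.0749 for Stard4, 0.0519 for Sc5d, 0.173 for Rps29, 0.106 for mt-Nd6, 0.1 for mt-Rnr2, 0.134 for mt-Co3, 0.102 for Cacna1c, 0.128 for Kcnq2, 0.0607 for Ret, 0.0738 for Mcm4, 0.122 for Lrp6 and 0.117 for Syt11. For some the log2 fold change moved little, as for Sqle (0.717 to 0.781), Sc5d (1.17 to 1.25) and Ret (0.931 to 1.03). For others it ranged more widely, as for Kcnq2 (0.702 to 1.45) and mt-Nd6 (0.946 to 1.6). Among genes named above, Zfp942 (edgeR adjusted p = 0.0507) was lost without miR-135a pulldown 1. Tnrc6b (adjusted p up to 0.0674) was lost without control pulldown 2 or 3 or miR-135a pulldown 1 or 3. Ago2 (adjusted p up to 0.0905) was lost without control pulldown 1 or 2 or miR-135a pulldown 1 or 3. With 1 library left out, the log2 fold change ranged from 1.26 to 2.23 for Tnrc6b and from 0.856 to 1.2 for Ago2. Acvr1b, Tgfbr1, Canx and Ncam1 stayed called whichever of the 6 was left out. camera gave an adjusted p of 0.862 against the other named genes for each of the TGF-beta, unfolded protein response, cholesterol synthesis, mitochondrially encoded and ribosomal protein lists, and the mitochondrially encoded list passed without control pulldown 2 (0.0438). Slc12a2, Dync1h1, Dclk1, Hist1h4j and Hist1h4k did not pass in the refit. None of the 25 reported miR-135 targets was among the named genes, nor was any gene of the glutamate synapse, nuclear respiratory, small nuclear or nucleolar RNA, nuclear long noncoding, interferon, p53 or 5 other-cell-type marker lists. A gene missing from the authors' list was not called higher by the authors, and its level was not analysed here. The authors called 587 genes higher of 10780 tested, the latter taken from the ratio of their false discovery rate to p. At that share, 0 of 25 says little about reported targets.

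Mef2a, a neuronal transcription factor, was named in advance from general knowledge of the study and not from its labels. It was at 23.5 ± 5.11 CPM in the control pulldown and 46.7 ± 16.6 CPM in the miR-135a pulldown (SD, n = 3 each). The log2 fold change of 0.98 (SE 0.292, edgeR adjusted p = 0.0494) passed narrowly, and over the alternatives the adjusted p ranged from 0.00469 with no filter on low counts to 0.14. The call was lost at a larger log2 fold change without control pulldown 2 (1.12, adjusted p = 0.0795), control pulldown 3 (1.03, 0.112) or miR-135a pulldown 1 (1.06, 0.114). It was lost at a smaller one with library size scaling (0.74, adjusted p = 0.14), without control pulldown 1 (0.83, 0.122), without miR-135a pulldown 3 (0.7, 0.134) and without both libraries that stood apart (0.51, 0.106). The gene lies on chromosome 7 from 67231163 to 67376456 (GRCm38.p6). The authors' predictions place a seed site in its 3′ UTR, at chromosome 7 from 67233818 to 67233840 (AACCTTGGAAAAAAAAAGCCATG, score 172, energy -18.03 kcal/mol).

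In all, 423 genes were higher and 877 lower in the miR-135a pulldown, of 10683 tested. The counts depended on the libraries and the scaling. Without miR-135a pulldown 1 they were 147 and 413, without control pulldown 2 186 and 519, without control pulldown 3 250 and 639, and without miR-135a pulldown 3 266 and 696. Library size scaling gave 188 and 996, with the median of all genes at -0.18, and leaving out both libraries that stood apart gave 1141 and 1598. The share of higher calls was 32.5% in the main test and 15.9% with library size scaling. Of the genes that fell, ENSMUSG00000014164, which the files do not pair with a name, went from 70 ± 12.4 to 1.82 ± 1.15 CPM (log2 fold change -5.32, edgeR adjusted p = 7.58e-05). ENSMUSG00000077505 had 69, 122 and 141 counts in the control pulldown and 0 in each miR-135a library. The authors' deposited table lists 587 higher and 1082 lower genes in the pulldown. These include all 423 and all 877 of the refit, and the edgeR exact test shared 573 and 1068 with them.

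**Figure D1:**
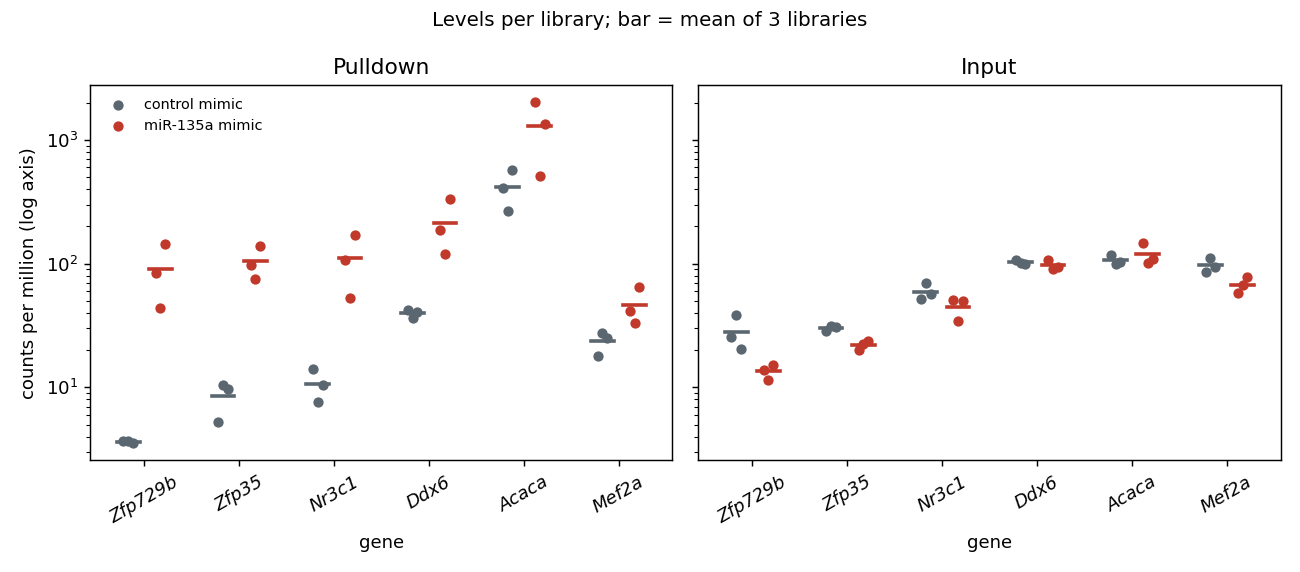
CPM on a log axis for 6 genes in each library of the pulldown (left) and the input (right); points are libraries, bars are means of 3, and colours mark the mimic. Zfp729b averages 3.64 CPM with the control mimic and 90.2 CPM with the miR-135a mimic in the pulldown.

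In the input, which shows what the mimic changed in the cells, no gene passed the threshold. Mef2a was at 97 ± 13.4 CPM with the control mimic and 67.7 ± 10.5 CPM with miR-135a (SD, n = 3 each; log2 fold change -0.52, SE 0.166, edgeR adjusted p = 0.548), with no overlap between the libraries of the 2 groups, which chance gives in 10% of genes. Zfp729b was at 28.1 ± 9.27 and 13.6 ± 1.96 CPM, and Zfp942 had a log2 fold change of -1.15 (SE 0.265, adjusted p = 0.431). edgeR's quasi-likelihood test called 0 of 13454 genes, with 1166 at an unadjusted p under 0.05, limma voom called 0, DESeq2 called 3 higher and 33 lower, and the edgeR exact test 4 and 27. The authors' deposited table lists 3 higher and 25 lower genes. Of these, Apoo (-0.91), Cldn12 (-0.94), Mettl9 (-1.31), Zfp729b (-1.05) and Zfp942 (-1.15), given with the authors' log2 fold changes and chosen after their values were seen, are also among the 587 genes higher in the pulldown. Another 6 of the 25, without names here, are among the 1082 genes the authors called lower in the pulldown.

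The named zinc finger genes lay lower in the miR-135a input as a list, with a median log2 fold change of -0.32 and 45 of 53 members below 0 (camera adjusted p = 3.76e-08). The call was lost with an estimated correlation (adjusted p = 0.475). fry, which asks whether the genes move 1 way and compares them with no others, gave an adjusted p of 0.269. Without 1 library at a time the camera adjusted p stayed at or below 4.82e-05. Without control input 2 the difference from the other genes was -0.13, against -0.33 with every library. The 10 axon guidance genes lay higher, with a median of 0.2 and 1 member below 0 (camera adjusted p = 0.00757; adjusted p = 0.252 with an estimated correlation), and without control input 3 the adjusted p was 0.0768. The other 6 lists did not pass in the main test: adjusted p was 0.106 for mitochondrially encoded, 0.37 for unfolded protein response, 0.605 for ribosomal protein, and 0.964 each for cholesterol synthesis, microRNA machinery and TGF-beta genes. The mitochondrially encoded genes lay lower, with a difference of -0.24. They passed with library size scaling (-0.31, adjusted p = 0.00172), without control input 2 (-0.4, 0.0148) and without miR-135a input 3 (-0.75, 0.00129), and without miR-135a input 1 the difference was 0.14.

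**Figure D2:**
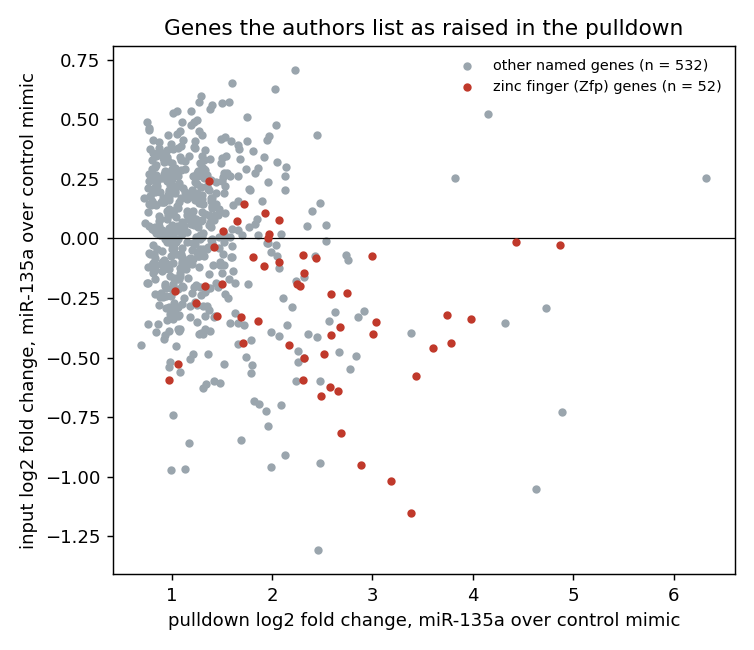
Log2 fold change (miR-135a over control mimic) in the pulldown on the horizontal axis and in the input on the vertical axis, for the named genes tested in both; each point is a gene, and red marks the 52 zinc finger genes. The red points have a pulldown median of 2.31, against 1.19 for the other named genes, and 45 of the 53 zinc finger genes tested in the input lie below 0 there.

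The authors' predicted sites were set against both fractions. Among the 587 genes, 402 had a predicted site, and seed sites lay in the 3′ UTR of 126 genes, the coding sequence of 167 and the 5′ UTR of 9. Seed sites were denser in coding sequences (15.6 per 100 kb) than in 3′ UTRs (10.4 per 100 kb) or 5′ UTRs (5.54 per 100 kb). The 53 zinc finger genes held 25.5% of the coding seed sites, at 0.644 per kb, against 0.124 per kb in the other named genes. No background rate of such matches was available. In the pulldown, named genes with a 3′ UTR seed site had a median log2 fold change of 1.19 against 1.18 for genes with no site (camera adjusted p = 0.454), and those with a coding seed site 1.31 (adjusted p = 0.0934). All of these genes had been selected as higher in the pulldown, which narrows any such difference. With an estimated correlation both had an adjusted p of 0.871. The coding value passed with library size scaling (adjusted p = 0.011), without both libraries that stood apart (0.0456), without control pulldown 1 (0.0141) and without miR-135a pulldown 2 (0.00593), and without the latter the 3′ UTR value passed too (0.0136).

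In the input, genes with a 3′ UTR seed site had a median log2 fold change of -0.1, and 81 of 126 lay below 0, against a median of 0.09 for the 171 genes with no site (difference -0.19, camera adjusted p = 1.6e-06; adjusted p = 0.146 with an estimated correlation). Those with a coding seed site had a median of -0.04 (difference -0.13, adjusted p = 0.00376; 0.263 with an estimated correlation). Without the zinc finger genes the 3′ UTR difference was -0.18 (adjusted p = 4.58e-06; 0.146 with an estimated correlation) and the coding difference -0.05 (adjusted p = 0.0916). The latter passed with genes matched on length (0.0277), without control input 2 (0.0153) and without miR-135a input 1 (0.0231).

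**Figure D3:**
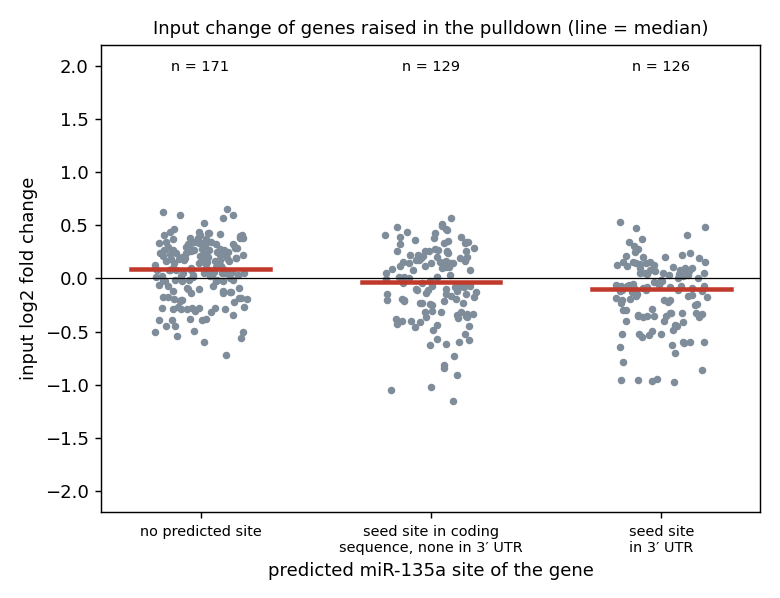
Input log2 fold change (miR-135a over control mimic) of named genes by predicted miR-135a site; points are genes and red lines are medians. The median is 0.09 for 171 genes with no site, -0.04 for 129 with a coding seed site alone, and -0.1 for 126 with a 3′ UTR seed site.

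Pulldown and input calls could not be compared by overlap in the main test, since the input had 0 calls. With the exact test in both, 5 of 24 genes lower in the input were higher in the pulldown, against 1.37 expected for independent lists (Fisher's exact test across genes, which are not independent replicates, p = 0.0102). A further 6 of the 24 were lower in the pulldown, against 2.44 expected. Across 10650 genes the 2 log2 fold changes had a Pearson correlation of 0.1 and a Spearman correlation of 0.12.

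The mimic effect in the pulldown was next tested against that in the input. Zfp729b (log2 difference 5.71, SE 0.479, edgeR adjusted p = 4.7e-06), Zfp729a (5.65), Zfp300 (4.92), Zfp942 (4.56), Zfp143 (4.47) and Rny3 (6.09) had the largest differences by the rule. Of 53 zinc finger genes 45 passed, as did Mef2a (1.54, SE 0.335, edgeR adjusted p = 0.0106) and Klf6 (2.91). Among all 587 named genes 313 were called higher. This fit, like those over input below, shares 1 spread (coefficient of variation 0.279) between the pulldown (0.366 alone) and the input (0.193 alone). Fitted with all 12 libraries, the pulldown comparison gave 1266 higher and 1421 lower genes, against 423 and 877 by itself. The edgeR adjusted p of Mef2a in the pulldown was then 0.00622, against 0.0494. Its difference was not examined with libraries left out. In all, 385 genes were higher and 576 lower of 13113, and 271 of the 423 genes higher in the pulldown alone were among the 385. Both tests use the same pulldown libraries, so part of this overlap is built in. Without miR-135a input 2 the counts were 154 and 308, without miR-135a input 1 176 and 414, without control input 2 202 and 477, without control input 1 211 and 358, and without miR-135a input 3 218 and 376. Without miR-135a pulldown 1 they were 263 and 380. Library size scaling gave 99 and 668, with the median of all genes at -0.32 and 12.9% of calls higher against 40.1% in the main test.

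The pulldown was also set against the input with each mimic. The genes named here had all been called higher with miR-135a, so they do not stand for all that the beads retained. Larger log2 rises over input belonged to genes without names. With the control mimic these were ENSMUSG00000097417 (11.85, SE 2.52) and ENSMUSG00000086844 (10.96, SE 1.93). With miR-135a they were ENSMUSG00000092909 (13.8, SE 2.46) and ENSMUSG00000028420 (9.03, SE 0.858). Their pulldown means were 13.2, 34.5, 1650 and 16000 CPM in that order. In all but the last the ratio rests on a very low input, so its size is uncertain. Of the 9 genes on the biotin carboxylase list, only Acaca was among the authors' genes. Acaca, which encodes a carboxylase that carries biotin, was higher in the pulldown with both mimics: 59.7 ± 6.01 CPM in the control input, 721 ± 266 in the control pulldown, 66.8 ± 13.4 in the miR-135a input and 2370 ± 1390 in the miR-135a pulldown (SD, n = 3 each). Its log2 fold change over input was 3.6 with the control mimic (SE 0.405, edgeR adjusted p = 7.54e-06) and 5.15 with miR-135a. Between the pulldowns alone Acaca was called higher with miR-135a (1.66, SE 0.44, adjusted p = 0.031), with overlap between the libraries of the 2 groups. That call was lost at nearly the same log2 fold change without control pulldown 1 (1.65, adjusted p = 0.09) or miR-135a pulldown 3 (1.65, 0.0727). It was lost at a smaller one with library size scaling (1.4, 0.0507), without control pulldown 2 (1.43, 0.107) and without miR-135a pulldown 1 (1.19, 0.156). It passed with DESeq2 (0.000228), with the exact test (0.00399) and without both libraries that stood apart (0.00301). The mimic effect in the pulldown did not pass against that in the input (adjusted p = 0.0826). mt-Nd6 (5.26 and 6.95) and mt-Cytb (4.63 and 5.63), both mitochondrially encoded, were higher with both mimics as well. Vaultrc5 (2.63 and 3.89), mt-Co3 (2.42 and 4.22) and Kmt2d (1.66 and 1.98) were likewise higher with both. The histone gene Hist1h4k (-2.63 and -1.49) and the translation factor gene Eif3e (-2.2 and -1) were lower with both.

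The named genes had been selected as higher in the miR-135a pulldown, so more of them above the input with miR-135a follows in part from that choice. Of the 423 genes higher in the miR-135a pulldown, 290 were above the input with miR-135a and 30 with the control mimic, and 122 were below it with the control mimic. Of the 877 genes lower in the miR-135a pulldown, 651 were above the input with the control mimic and 161 below it with miR-135a. The comparisons share pulldown libraries, so part of these overlaps is built in. With the control mimic 0 of 53 zinc finger genes were higher in the pulldown than in the input and 5 were lower, and with miR-135a 46 were higher and 0 lower. Zfp35 had a log2 fold change over input of -0.17 with the control mimic (adjusted p = 0.645) and 3.93 with miR-135a (adjusted p = 2.52e-07). All 6 microRNA machinery genes and 9 of 10 axon guidance genes were higher over input with miR-135a, against 2 and 0 with the control mimic. In the test of the difference between the mimic effects 4 of 6 and 4 of 10 passed, as did 313 of the 587 named genes. These counts therefore do not set the 2 lists apart from the named genes. Over all genes, 2024 were higher and 1812 lower with the control mimic, and 1478 and 1010 with miR-135a, of 13113. Without miR-135a input 1 the miR-135a counts were 860 and 568, without miR-135a input 2 934 and 437, without miR-135a input 3 975 and 546, without miR-135a pulldown 1 1189 and 619, and without miR-135a pulldown 3 1003 and 578. With library size scaling the median of all genes moved to -1.53 and -1.89, and 422 and 132 genes were higher against 9231 and 10441 lower, so each direction over input is relative to the other genes.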

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

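The test that the mimic effect differs between pulldown and input picked out 385 genes with a higher and 576 with a lower effect in the pulldown. The largest named differences by the rule were Rny3 (log2 difference 6.09), Zfp729b (5.71), Zfp729a (5.65), Zfp300 (4.92), Zfp942 (4.56) and Zfp143 (4.47). Groups of 3 libraries were too small for a search for single outlying libraries. The counts of other splits for the pulldown and for the input were planned only after their calls had been seen.

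Of 100 drawn splits of the 12 libraries within fraction, 6 gave at least the 961 calls of the real one, with a highest other count of 1298, so chance is not excluded for this count. All 6 kept the true split of the pulldown libraries, as 12 of the 100 did, and no split that mixed the pulldown libraries gave any call. The structure of the count thus lies in the pulldown libraries, and mixing the input libraries raised or lowered it.

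For the comparisons of 3 libraries against 3 there are only 10 splits, too few for a share under 0.05. The pulldown gave 1300 calls in the real split and at most 0 in another, so 1 of 10 splits reached that count. The input gave 0 calls in the real split and at most 1 in another, so 10 of 10 did. The pulldown over input gave 3836 calls with the control mimic and 2488 with miR-135a, each with 0 as the highest other count.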

How the results depend on the processing

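No paired analysis was possible because the count columns carry no replicate numbers. The replicate block and the mimic-by-number block were therefore not run. fry in the pulldown was not run because it compares a list with no other genes. Leaving out both pulldown libraries that stood apart, and the exact test for shared calls, were chosen after seeing the data. The causes of the changes below were not tested, except that leaving out libraries lowers the number of samples.

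Genes higher in the pulldown numbered 711 with DESeq2, 188 with library size scaling, 678 with no filter, 1266 with all 12 libraries in one fit and 1141 without both libraries that stood apart; genes lower numbered 1421 and 1598 in the last 2. Leaving out 1 library gave 147 to 370 higher and 413 to 769 lower. In the input, DESeq2 gave 3 higher and 33 lower, library size scaling 7 and 28, no filter 66 and 205, the exact test 4 and 27, and leaving out 1 library 0 to 2 and 0 to 6. For the difference of mimic effects, DESeq2 gave 764 and 1010, library size scaling 99 higher, leaving out both libraries that stood apart 723 and 873, and leaving out 1 library 154 to 513 and 308 to 640. Over input, library size scaling gave 422 and 9231 with the control mimic and 132 and 10441 with miR-135a, where leaving out 1 library gave 860 to 1566 and 437 to 1321.

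Of the lists in the pulldown, 0 passed in the main test, 2 with library size scaling, 1 without both libraries that stood apart and 0 to 1 without 1 library. The zinc finger difference passed at 1.1 with library size scaling and at 0.806 without both libraries. The 3′ UTR site difference in the pulldown changed sign to -0.0166 with library size scaling and -0.0572 without both libraries, and ranged from -0.0566 to 0.105 without 1 library; without zinc finger genes it was 0.0366 with the 5 CPM filter, 0.0267 with sites of any transcript and -0.0734 to 0.0542 without 1 library. The coding site difference passed at 0.136 with library size scaling and 0.0958 without both libraries, and ranged from 0.0933 to 0.204 without 1 library; without zinc finger genes it was -0.00623 without both libraries and -0.0203 to 0.0948 without 1. Axon guidance in the pulldown was 0.0118 with the 5 CPM filter and -0.0569 to 0.019 without 1 library, and microRNA machinery -0.00148 to 0.487, passing at 0.237 with library size scaling and at 0.487 without miR-135a pulldown 2.

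In the input, 2 lists passed in the main test and 0 with an estimated correlation, where axon guidance (0.195), zinc finger genes (-0.328), 3′ UTR sites (-0.192) and coding sites (-0.131) all lost their calls with the differences unchanged. fry, which tests a list against no change and not against other genes, passed 0 lists; 1 to 3 lists passed without 1 library, and axon guidance ranged from 0.13 to 0.229. Differences that changed sign without 1 library ranged from -0.112 to 0.0561 for cholesterol synthesis, -0.265 to 0.0262 for ribosomal protein, -0.104 to 0.0455 for microRNA machinery, -0.752 to 0.143 for mitochondrially encoded and -0.156 to 0.0916 for TGF-beta genes. Of these, the mitochondrially encoded list passed at -0.314 with library size scaling, at -0.402 without control input 2 and at -0.752 without miR-135a input 3.

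Of the single genes picked by the rule, those that changed sign did so in the input, where none was called. Without 1 library their log2 fold changes ranged from -0.0253 to 0.26 for Acaca, -0.0304 to 0.351 for Mcm3, -0.208 to 0.177 for Mcm4, -0.192 to 0.0562 for Sc5d, -0.165 to 0.135 for Dclk1, -0.557 to 0.013 for Rpl39, -0.263 to 0.0377 for Rps29, -0.0501 to 0.15 for Rps18, -0.169 to 0.105 for Slc12a2, -0.857 to 0.0786 for mt-Nd6, -0.411 to 0.197 for mt-Cytb, -0.61 to 0.334 for mt-Rnr2, -0.353 to 0.0593 for Tgfbr1 and -0.178 to 0.147 for Skil. With library size scaling Dclk1 was 0.0185, Slc12a2 0.0496 and Skil 0.0928, and Skil was 0.0159 with upper quartile factors.

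Genes higher in the pulldown and lower in the input numbered 1 at an adjusted p under 0.1, 3 with library size scaling, 5 with the exact test and 0 to 2 without 1 library. The exact test shared 3 higher and 24 lower input genes with the authors' table. Predicted sites covered 144 genes at the higher score threshold and 129 at an energy of at most -20 kcal/mol.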

Other observations

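Chosen after the results were seen were the tests of zinc finger genes and of 3′ UTR sites in the input, of the linker codons, of coding length and expression, and of sequencing depth. The other tests here were set before their results were seen.

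Most coding seed sites of the zinc finger genes shared a reading frame, 55 of 63 against 47 of 184 in the other named genes. The match to the seed, AAGCCATA in its longest form, reads Lys-Pro from its first base, and the linker between neighbouring C2H2 zinc fingers commonly holds Glu-Lys-Pro. Of 63 coding seed sites in the zinc finger genes, 40 (63.5%) were in frame behind a Glu codon, against 10 of 184 (5.43%) in the other named genes (Fisher's exact test across sites, which are not independent, p = 1.35e-20). Those 10 lay in 8 genes: Bach1, Mtf1, Mynn, Tet3, Zeb1, Zfp354c, Zfp729a and Zfp729b. In Zfp35 both coding sites are of this kind, at coding positions 795 to 815 (CCACACTGGGGAGAAGCCATA) and 1551 to 1571. A candidate explanation for the sites is thus the repeated linker sequence. Zinc finger genes that were not raised have no names or sequences here, so whether they hold fewer such sites was not tested.

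Zinc finger genes led the miR-135a pulldown by log2 fold change, although camera did not separate their list from the other named genes (adjusted p = 0.862). Low counts as a source of this lead were tested only in part. The zinc finger median exceeded that of other named genes matched on mean expression by over 0.5 in 100% of 10000 draws (2.31 against 1.45). That mean covers both mimics and so includes the rise itself, which leaves low counts in the control pulldown unmatched. Reads shared between near-identical copies stay open: the 4 named genes that share a number lie outside the list, so a median of 2.31 without them tests nothing. Coding sites remain as a hypothesis: they were 5.19 times as dense as in the other named genes, and their number rose with the pulldown log2 fold change across 52 zinc finger genes (Spearman rho 0.465, Pearson 0.444, permutation p = 0.00061 for rho), which are not independent replicates and were all selected as raised. With coding length and mean expression over both mimics held, the partial rank correlation was 0.495 (permutation p = 0.00021). Across 523 other named genes rho was 0.0128 (permutation p = 0.77).

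That captured RNAs as a whole would be lower in the input was a hypothesis set beforehand, and the data went against it: the 587 named genes had a median of 0.01, as did the others (camera adjusted p = 0.856). With library size scaling the difference from the others was -6.36e-05, and 98.5% of expression-matched lists had a median as low. All 10 splits of the input libraries gave a difference on mean log2 CPM at least as large as the real 0.00365, with a highest other of 0.0826.

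Within these genes, those with seed sites lay lower in the input. For sites in the 3′ UTR or coding sequence the medians were -0.08 over 255 genes and 0.09 over 171 genes without a site, a difference of -0.17. camera compared these 255 and 171 genes alone, with weights from all tested genes and correlations between genes set at 0.01. Its unadjusted p was 5.08e-05, which met the criterion written beforehand. The estimated correlation, not part of that criterion, gave 0.137, so silencing through the sites may contribute but is not settled. For 3′ UTR sites alone, matching on 3′ UTR length left 92.6% of the difference. Matches for 126 genes came from only 171 genes without a site, and the balance in length reached was not measured. Length as a source therefore stays open. For the zinc finger genes 0 of 10000 expression-matched lists had a median as low, which argues against expression level. Library size scaling left 103% and 97.3% of the 2 differences, but it moves nearly all genes alike (median shift 0.0976, interquartile range 0.0205), so this tests nothing. The 10 splits of the input libraries are too few for a share under 0.05. Measured there on mean log2 CPM rather than on fitted fold changes, 1 of 10 reached the real difference in both cases, which was 0.267 in size for zinc finger genes and 0.203 for 3′ UTR sites, but the highest other splits came close at 0.247 and 0.184.

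Control pulldown 1 and miR-135a pulldown 3 stood apart from the other 4 pulldown libraries. Depth does not account for it: thinned to 7597489 counts each, the higher of them still detected 1400 fewer genes than the lowest of the others, whose own range was 854. The share of the 10 most abundant genes was 64.8% in control pulldown 1, inside the range of 58.4% to 73% of the other 4. That range mixes the mimics, and the other control pulldowns had lower shares, 63.7% and 58.4%. In miR-135a pulldown 3 the share was 75.3%, above that range and above the 73% and 72.2% of its own group. The criterion set beforehand against a few dominant genes, a share inside that range in either library, was met. With shares of 73% and 72.2%, miR-135a pulldowns 1 and 2 still detected 13959 and 13880 genes after thinning, against 12146 in control pulldown 1. These values argue against a few dominant genes for control pulldown 1. For miR-135a pulldown 3 that explanation stays open. Both libraries that stood apart lie in different groups, and no biological explanation was tested.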
